A study of Mus musculus with 3 samples.

How the data were processed

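Serum miRNA was measured on the NanoString nCounter Mouse v1.5 miRNA panel, which counts fluorescent barcodes hybridized to each miRNA without amplification. Per the labels' protocols, mice received 100000 4T1 cells in a mammary fat pad and were killed on day 28. RNA was extracted from 200 µL of serum into 20 µL, and about 30 ng was hybridized for 16.5 h with barcodes for 527 mouse miRNAs. Groups held 8 or more animals per the labels, and serum was pooled within group because little was available per animal. The pools were 2 Tn+ and 1 Tn-, grouped by their titles.

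The deposited table holds a normalized signal per probe and pool, made by the authors with the nCounter Advanced Analysis Software per the series' design text. R 4.4 is named in the submitters' processing notes. The probes used for scaling, the background method and the floor are not given in the sources used here. All 566 probes are endogenous miRNA probes, so control probes were not analysed here. A second deposited table holds the same signal, with 1698 of 1698 values equal. Within each pool the signal above the floor fell on a regular grid. All 200, 126 and 78 values of up to 60 units in Tn+ pool 1, Tn+ pool 2 and the Tn- pool lay within 0.05 steps of a whole number of steps from the lowest value above the floor. The step was 0.896, 1.09 and 1.08 units. Such a grid is what whole counts times 1 factor, less a constant background, would give. The floor was 1, 1.09 and 1.08 units, shared by 338, 416 and 481 probes. The number of counts subtracted as background is unknown, so whole counts could not be recovered and no count model was used. Totals were not equalised between pools by the authors.

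The design fixed before the data were examined assumed whole counts and a count model, and foresaw limma where only normalized values were present. Log2(signal + 1) was fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), all 566 probes and 3 pools, no covariate, and Benjamini-Hochberg adjustment at 0.05. Fold changes on this scale understate changes of low miRNAs. With 2 Tn+ pools and 1 Tn- pool there is 1 residual degree of freedom, and the Tn- pool is assumed to vary like the Tn+ pools. A rule of size, without a p-value, counted probes at least 2-fold apart from the Tn- pool in both Tn+ pools. Values of this rule are on signal + 1. For a miRNA at the floor in the Tn- pool, its Tn+ signal is given over 3 grid steps (3.23 units) in the Tn- pool, on the deposited scale. That ratio is not a lower limit, since the counting error of the subtracted background is unknown. A probe is called detected when above the floor in at least 1 pool.

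The 18 miRNA lists (cell type markers, families, genomic clusters and breast cancer miRNAs) were fixed in advance. For each, the median log2 ratio of its detected members was placed among 10000 random lists of the same size, drawn within 5 classes of mean level, as a description of these pools. Passing members were counted after adjustment over all probes and over the list alone. Named miRNAs were all those past the adjusted threshold in the fixed fit, the 12 largest increases and 12 largest decreases with both Tn+ pools on 1 side of the Tn- pool by more than they differ, the 10 highest by mean level, and up to 4 members of each list with the largest absolute ratio. Any other miRNA named was chosen after its values were seen. The Dlk1-Dio3, Sfmbt2, let-7, miR-17 cluster and miR-30 lists hold closely related members whose probes can share signal, and 9 probes name several miRNAs. Shared signal was not tested, so counts of members in these lists may not be counts of separate miRNAs. Gene names for probes were matched to RefSeq (GRCm38.p6), where 529 of 566 probes had a miRNA gene and 37 had none. Gene positions from the same table were used only to pair miRNA genes within 10 kb of each other. Mature sequences were not used here.

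The limma script was tested on 20 simulated sets of 566 probes with 200 changed. Over all probes it found 0% of 4-fold and 0% of 16-fold changes and made no false call. Restricted to probes with a mean of 10 or more (105 on average), it found 2.65% of 4-fold and 14.6% of 16-fold changes, and 2.11% of its calls were false. The simulated changes went in both directions, with no shift shared by a pool, and more probes passed the filter than the 58 here. These rates therefore do not carry over to the filtered fits below. The changed probes were drawn from all 566, including the 307 at the floor in every pool, where a decrease could hardly show. Those 307 were simulated with counting noise, which their tied deposited values lack. The 0% is therefore not the power of the fit over all probes for well-measured miRNAs. The fitted ratio recovered 0.974 of the true log2 change in the restricted probes. The list percentile was tested by planting a log2 shift of 2 in each of 12 lists, and 10 were then at or above the 97.5th percentile. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 was used for everything else.

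Alternatives were equal totals, the geometric mean of the 100 highest probes and the median of ratios (each with a common floor set after scaling, since scaling puts the floors at different heights), a pseudocount of 10, thresholds of 1.5-fold and 3-fold, the second table, and each Tn+ pool left out. Filters on low probes, a common floor on the deposited scale, a variance trend and scaled limma fits on filtered probes were added after seeing the data. Settings that need counts or control probes were not run: edgeR, DESeq2 and TMM, positive control scaling, background limits from negative controls, and background subtraction, which the table already carries.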

Results

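Circulating miRNAs were profiled in serum of mice carrying 4T1 mammary tumours, a mouse model of triple-negative breast cancer, that differed in Tn antigen. Tn is a truncated O-glycan exposed on the cell surface when O-glycan chains are not extended. Per the labels' protocols, Tn+ 4T1 cells were made by CRISPR/Cas9 targeting of Cosmc, the chaperone that O-glycan extension needs. The panel measures miRNAs, so Cosmc itself was not measured and the edit could not be checked here. Serum was pooled by tumour Tn status before RNA extraction, and the comparison asks which cell-free miRNAs differ with that status. The data are 3 pools, 2 from mice with Tn+ tumours and 1 from mice with Tn- tumours. Nothing in the labels says how many mice each pool holds, or whether the 2 Tn+ pools came from separate mice. P-values therefore measure only the spread between these pools, and the Tn- pool has no replicate.

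Of 566 probes, 228 lay above the lowest deposited value (the floor) in Tn+ pool 1, 150 in Tn+ pool 2 and 85 in the Tn- pool. Only 60 probes lay above the floor in all 3 pools, and 307 lay at the floor in every pool. The summed normalized signal was 59444 units in Tn+ pool 1, 31977 in Tn+ pool 2 and 4204 in the Tn- pool. The total was thus 14.1-fold higher in Tn+ pool 1, and 7.61-fold higher in Tn+ pool 2, than in the Tn- pool, while the Tn+ pools differed from each other by 1.86-fold. Without miR-451 the totals were still 6.99-fold and 8.01-fold higher. Precision was limited accordingly in the Tn- pool, where 18 probes reached 20 units, against 49 and 47 in the Tn+ pools. Low values lay on a grid with steps of 0.896 units in Tn+ pool 1, 1.09 in Tn+ pool 2 and 1.08 in the Tn- pool, so differences of a few units are differences of a few steps.

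The most abundant miRNA in each pool was miR-451 (MIMAT0001632), an erythrocyte miRNA, at 43043 and 13159 units in the Tn+ pools and 1856 in the Tn- pool. It made up 72.4%, 41.2% and 44.1% of the signal of these pools. The other probes among the 10 highest by mean level were miR-25, miR-1224, miR-16, miR-486, the shared probe for miR-20a and miR-20b, miR-2137, miR-223, the shared probe for miR-106a and miR-17, and miR-144. Of these, miR-16 had 2058 ± 780 units in Tn+ serum (SD, n = 2) and 176 in the Tn- pool, and miR-486, another erythrocyte miRNA, had 1663 ± 855 against 98.6. miR-25 had 3690 ± 2577 units against 104. miR-1224 had 2831 ± 1039 against 452, and miR-2137 had 547 ± 452 against 27.4. The smallest ratio among the 10 belonged to miR-223, a myeloid and platelet miRNA, with 719 and 225 units in the Tn+ pools and 136 in the Tn- pool, and it turned negative under all 3 scalings given further on. That of miR-1224 did so with equal totals and top-100 scaling.

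**Figure D1:**
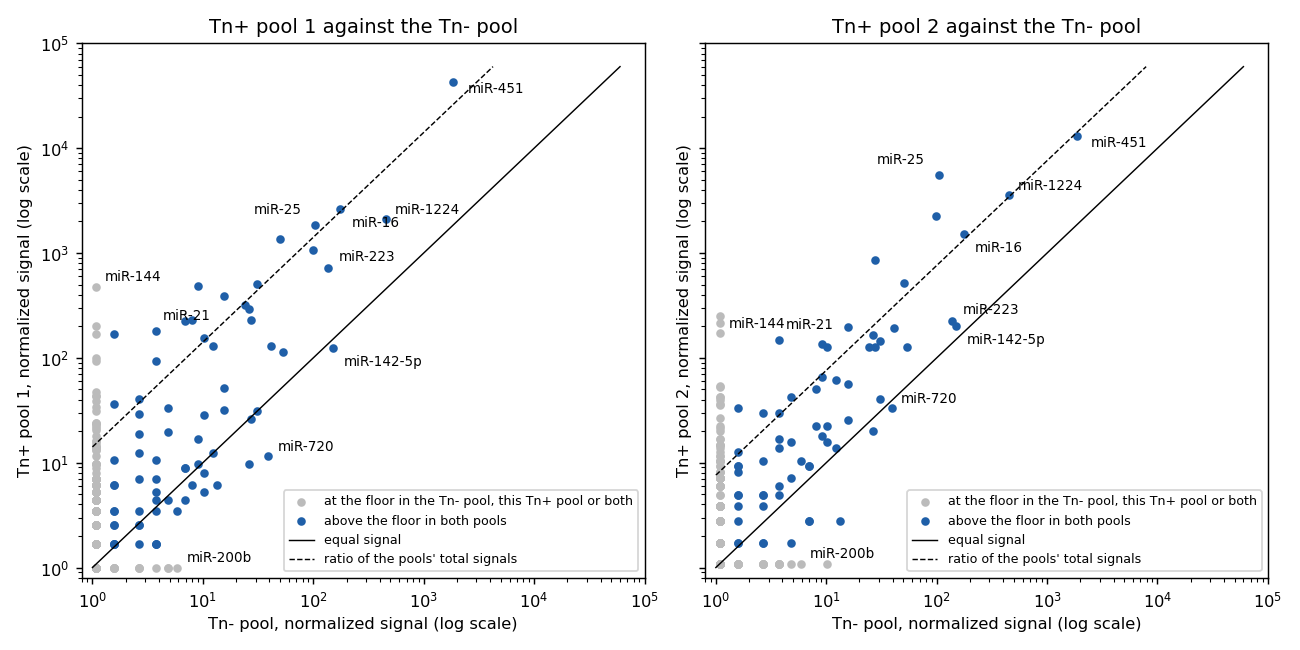
Normalized signal of each of 566 probes in Tn+ pool 1 (left) and Tn+ pool 2 (right) against the Tn- pool, both axes logarithmic, with grey points for probes at the floor in either pool shown; the solid line marks equal signal and the dashed line the ratio of the pools' totals. Most probes above the floor lie over the solid line, with miR-451 at 43043 and 13159 units against 1856, while miR-142-5p and miR-720 lie near or below it; relative to equal totals, 10 probes were at least 2-fold higher and 39 lower in both Tn+ pools.

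On the deposited scale most miRNAs above the floor in all pools had more signal in Tn+ than in Tn- serum. Among the 60 probes above the floor in all pools, 43 were higher in both Tn+ pools and 4 were lower in both. The median log2 ratio over these probes was 1.58 for Tn+ pool 1 and 1.86 for Tn+ pool 2, against -0.12 between the Tn+ pools. Both Tn+ pools were at least 2-fold above the Tn- pool for 68 probes and at least 2-fold below it for 4, on signal + 1. Pool 1 alone was so for 120 and 7 probes, and pool 2 alone for 96 and 12. For scale, the 2 Tn+ pools differed from each other by at least 2-fold for 112 probes. Of the 68, 40 were at the floor in the Tn- pool, and 23 of these 40 were still at least 2-fold higher in both Tn+ pools when 3 grid steps were set for the Tn- pool, which leaves 51. The rest of the 68 kept their Tn- value, also where it lay under 3 steps, as for miR-326 (6.15 and 12.6 units against 1.58).

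The 12 largest ratios for which the Tn+ pools lay closer to each other than to the Tn- pool included miR-144, let-7i, let-7b and miR-106b, all at the floor in the Tn- pool, so that their order depends on the value of the floor. miR-144, encoded beside miR-451 and abundant in red cells, had 477 and 171 units in the Tn+ pools, 148-fold and 53.0-fold above 3 grid steps in the Tn- pool on the deposited scale. The corresponding ratios to 3 steps were 52.0-fold and 65.8-fold for let-7i, 28.8-fold and 76.9-fold for let-7b, and 62.3-fold and 16.7-fold for miR-106b, a paralogue of the miR-17 cluster. Measured in all pools were miR-21, an abundant miRNA of tumours and myeloid cells, with 165 ± 23.4 units (SD, n = 2) against 3.73, and miR-25. Also measured in all pools were let-7g (489 and 134 units against 9.12), miR-23a (393 and 199 against 15.6) and the miR-20a and miR-20b probe (1364 and 515 against 50.1). miR-15a had 167 and 33.3 units against 1.58, which is above the floor in the Tn- pool but under 3 grid steps (3.23 units). miR-425 had 42.9 and 42.0 units, 13.3-fold and 13.0-fold above 3 steps in the Tn- pool, and the endothelial miR-126-3p had 42.9 and 35.4 units against the floor.

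The 12 lowest ratios picked by the same rule were small in absolute terms. The Tn- pool had 13.4 units of miR-465c-5p, against 6.15 and 2.79 in the Tn+ pools, and 5.89 units of miR-200b, a miRNA of epithelial cells, against the floor in both Tn+ pools. It had 6.96 units of miR-345-3p against 4.36 and 2.79, and 4.81 units of miR-666-5p against the floor and 1.70. The other 8, miR-743b-3p, miR-7b, miR-1939, miR-380-5p, miR-682, miR-509-3p, miR-695 and miR-1893, had 3.73 units or less in the Tn- pool.

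With limma on log2(signal + 1) over all 566 probes, the fit fixed in advance, no miRNA passed an adjusted p of 0.05. The smallest adjusted p was 0.117, shared by miR-425, let-7i, miR-21, miR-205 and miR-126-3p. An unadjusted p under 0.05 was reached by 63 probes, 56 higher and 7 lower in Tn+ serum. The 307 probes at the floor in every pool share the same values and could not reach it. A share of 0.05 of the other 259 is 12.95, but the shift between pools leaves no valid chance count. Among the 7 lower, miR-200b, miR-743b-3p, miR-380-5p and miR-682 were at the floor in both Tn+ pools. Their SE therefore holds no spread of the miRNA. In simulated pools the fit over all probes found 0% of 16-fold changes. These were planted over all 566 probes, most of them near the floor, so the rate is not its power for well-measured miRNAs. Restricted after seeing the data to the 259 probes above the floor in at least 1 pool, limma called 29 miRNAs, all higher in Tn+ serum. The 29 all belonged to the 68 of the size rule, and they included miR-144 (log2 ratio 7.11, SE 1.15, adjusted p = 5.59e-07), let-7i (6.51, adjusted p = 4.53e-06), let-7b, miR-106b, miR-21, miR-25, miR-122 and miR-451. For miR-144 the adjusted p was 0.243 over all 566 probes, and it ranged from 1.13e-04 to 0.336 over the fits to the 58 probes with a mean of 10 or more, deposited and scaled. The filtered fit gave every probe the same SE, pooled over the 259 probes, so its calls follow the size of the ratio. Its p-values take that SE as known, though probes are not replicate pools. Only 7 of the 259 were above the floor in the Tn- pool alone, so the filter favoured higher Tn+ signal. Both fits have 1 residual degree of freedom per probe, from the Tn+ pools alone, and assume that Tn- serum varies likewise.

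Because the pools differ in total, the ratios were also expressed relative to that shift. Scaling by the median of ratios over the 60 shared probes removed a 3.18-fold difference, scaling by the geometric mean of the 100 highest probes a 6.06-fold difference, and equal totals a 10.4-fold difference. After the median-of-ratios scaling, 33 probes were at least 2-fold higher in both Tn+ pools and 21 at least 2-fold lower. All 33 were among the 68 of the deposited scale, while only 6 of the 21 had a mean of 10 or more as deposited. The Tn+ pools differed from each other by at least 2-fold for 61 probes after this scaling. The log2 ratio was then 5.87 for miR-144, 5.28 for let-7i, 4.97 for let-7b, 4.43 for miR-106b, 3.63 for miR-21, 2.01 for miR-451 and -0.11 for miR-223. Some well-measured probes moved to the Tn- side, and the following were chosen after their values were seen. miR-142-5p, a blood cell miRNA, had 163 ± 54.1 units in Tn+ serum (SD, n = 2) and 150 in the Tn- pool, a log2 ratio of 0.07 as deposited and -1.59 scaled. let-7f had 36.0 ± 6.82 units against 30.7, and -1.41 scaled. With limma on the 58 probes with a mean of 10 or more, no probe passed an adjusted p of 0.05 after this scaling or the top-100 scaling (smallest adjusted p 0.129 and 0.336; 9 and 8 at an unadjusted p under 0.05). With equal totals 4 passed, with miR-144 and let-7i higher and miR-720 and miR-202-5p lower in Tn+ serum.

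Erythrocyte miRNAs held most of the signal in every pool. The 8 probes of the list took 82.9% of the signal in Tn+ pool 1, 70.8% in Tn+ pool 2 and 53.5% in the Tn- pool. Of the 7 above the floor in some pool, 5 (miR-144, miR-25, miR-486, miR-451 and miR-16) were at least 2-fold higher in both Tn+ pools and none was lower. The other 2 were miR-15b, with 226 and 9.32 units against 6.96 (lower with equal totals), and miR-92a, with 7.05 units and the floor against 3.73. The list median log2 ratio was 4.15 and 3.09 in the Tn+ pools. The median of the mean ratios was 3.68, the 86.9th percentile of random lists of like level, and also 3.68 with floor values at 3 grid steps. With equal totals that median was 0.31. None of its members passed limma over all probes (5 at an unadjusted p under 0.05), and 4 passed when adjusted over the list alone. The ratio of miR-451 to miR-23a, a haemolysis index of serum, was 110 and 66.2 in the Tn+ pools and 119 in the Tn- pool.

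The let-7 family, which restrains growth and stemness programmes in many tissues, had a list median of the mean ratios of 3.94, or 3.26 at 3 steps, with 3.95 and 3.74 in the single Tn+ pools and 1.32 for the mean ratios with equal totals. Of its 7 detected members, let-7i, let-7b, let-7g, let-7c and let-7d were at least 2-fold higher in both, while let-7f and miR-98 were not, and let-7a and let-7e were at the floor in all pools. None passed limma over all probes (5 at an unadjusted p under 0.05) and 3 did when adjusted over the list alone. The 8 detected probes of the miR-17 cluster and its paralogues, which promote proliferation, had medians of 4.20 and 3.02, and 3.49 for the mean ratios at 3 steps or 0.56 with equal totals. Of these, 7 were at least 2-fold higher in both pools, among them miR-106b, miR-25, miR-20a with miR-20b, and miR-93, and none passed either adjustment in limma (6 at an unadjusted p under 0.05). The miR-106a and miR-17 probe turned lower with equal totals, and miR-19b, with 28.5 and 22.4 units against 10.2, turned lower under all 3 scalings (log2 ratio -0.34, -1.23 and -1.97 after median-of-ratios, top-100 and equal-total scaling). In the miR-30 family 4 of 5 members were at least 2-fold higher in both Tn+ pools, namely miR-30c, miR-30d, miR-30e (lower with equal totals) and miR-30b. The medians were 2.17 and 1.97, and 1.62 for the mean ratios at 3 steps or 0 with equal totals, and 2 passed when adjusted over the list alone.

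Of the miRNAs reported to promote breast cancer, 6 of 15 were detected and 4 were at least 2-fold higher in both Tn+ pools. These were miR-21, miR-23a, miR-122 and miR-27a (141 ± 19.8 units, SD, n = 2, against 10.2). Their list medians were 4.17 and 3.50, and that of the mean ratios, 3.83, lay at the 98.0th percentile of random lists, with 3.56 at 3 steps or 0.59 with equal totals, and 2 members passed when adjusted over the list alone. miR-10b, miR-9, miR-155, miR-221 and miR-222 were at the floor in all pools. Of 22 probes for miRNAs reported to suppress breast cancer, 13 were detected, 5 of them at least 2-fold higher in both Tn+ pools and none lower. Its largest ratios belonged to miR-126-3p, miR-125b-5p, miR-205 and miR-146a. Against 3 grid steps in the Tn- pool, miR-125b-5p (1.90-fold in Tn+ pool 1) and miR-146a (1.20-fold in Tn+ pool 2) were among those no longer 2-fold higher in both. The list median was 1.37 and 0.87, and for the mean ratios 0.80, the 76.1st percentile, with 0.36 at 3 steps or 0 with equal totals, and 2 members passed when adjusted over the list alone.

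Markers of blood and tissue cell types other than red cells differed between lists. The lymphocyte list had medians of 3.23 and 1.23, and for the mean ratios 2.37, the 99.3rd percentile, with 1.54 at 3 steps or 0.05 with equal totals, with 5 of 8 detected probes at least 2-fold higher in both pools. Its largest ratios were those of miR-342-3p (100 and 10.4 units against the floor), miR-150 (318 and 126 against 24.2, but lower with equal totals), miR-29c and miR-29a, and none passed either adjustment in limma (2 at an unadjusted p under 0.05). With floors at 3 grid steps miR-29a and miR-146a, each at 3.88 units in Tn+ pool 2, no longer met the rule. The list median of 2.37 lies between their ratios, and its percentile was not recomputed at 3 steps. miR-342-5p, at the floor and 7.14 units against 4.81, had a log2 ratio of -0.53. In the myeloid list 3 of 5 detected probes met the size rule, namely miR-21, miR-142-3p and miR-146a. With floors at 3 grid steps miR-146a, at 21.4 and 3.88 units, no longer met it. miR-223 did not meet the rule, nor did miR-142-5p, from the same gene as miR-142-3p, with 124 and 201 units against 150. The medians were 3.43 and 1.23 (for the mean ratios 1.56 at 3 steps and 0.21 with equal totals), and 1 member passed when adjusted over the list alone. The list took 1.82% and 1.86% of the signal of the Tn+ pools and 7.03% of the Tn- pool. In the platelet and endothelium list 2 of 6 detected probes met the rule, miR-126-3p and miR-191, and the medians were 1.99 and 0.55 (for the mean ratios 0.96 at 3 steps and 0 with equal totals). miR-199a-3p had 7.94 units and the floor against 10.2. Adjusted over the list alone, 2 members passed.

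Of the liver list, miR-122, the main hepatocyte miRNA, had 47.3 and 22.4 units and was at the floor in the Tn- pool, 14.6-fold and 6.92-fold above 3 steps on the deposited scale. Its log2 ratio was 4.01 as deposited, 2.80 after median-of-ratios scaling and 1.38 with equal totals. miR-148a had 230 and 50.7 units against 8.04, while miR-101b had 5.26 and 15.9 against 10.2. The liver medians were 4.54 and 2.51 (for the mean ratios 3.33 at 3 steps and 0.37 with equal totals), and none passed either adjustment in limma (1 at an unadjusted p under 0.05). In the epithelial list miR-205 had 29.7 ± 0.396 units in Tn+ serum (SD, n = 2) and 2.65 in the Tn- pool. miR-429 and miR-203 had 5.26 to 7.05 units against the floor, and miR-200b was higher in the Tn- pool. These 4 were its only detected members and passed when adjusted over the list alone, 3 higher and 1 lower in Tn+ serum. The lower one, miR-200b, was at the floor in both Tn+ pools. Its SE of 0.1575 equals that of probes at the floor in every pool, so its p measures no spread of the miRNA. The list medians were 1.77 and 1.76 (for the mean ratios 0.91 at 3 steps and 0 with equal totals). In the pancreas and endocrine list miR-7a (22.3 and 26.7 units against the floor) was 6.89-fold and 8.27-fold above 3 steps on the deposited scale and was the 1 member to pass when adjusted over the list alone. Its log2 ratio was 3.61 as deposited, 2.40 after median-of-ratios scaling and 1.00 with equal totals. miR-375 had 6.15 and 22.4 units against 8.04. The list medians were 0.01 and 0.69 (0.21 at 3 steps), and that of the mean ratios was -0.51, -0.77 and -0.81 after median-of-ratios, top-100 and equal-total scaling. The muscle and heart medians were 0.41 and -0.15 (-0.06 at 3 steps), also negative under these 3 scalings, and the nervous system medians were 0.79 and 0.01 (0.66 at 3 steps and 0 with equal totals). The -0.06 comes from members set to 3 grid steps in the pools, whose heights differ, and not from lower signal in Tn+ serum. No muscle, nervous system or embryonic stem cell miRNA met the size rule in either direction, and none reached 10 units in any pool. In these 3 lists none passed limma, also at an unadjusted p under 0.05.

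Large imprinted or clustered groups had low signal in all pools. Of 58 probes of the Dlk1-Dio3 cluster 24 were detected, with 2 (miR-431 and miR-299) at least 2-fold higher in both Tn+ pools and 1 (miR-666-5p) lower; miR-431 turned lower with equal totals and top-100 scaling. The medians were 0.78 and 0.04 (0.06 at 3 steps and 0 with equal totals). In the Sfmbt2 cluster 4 of 20 detected probes were higher, led by miR-466g at 9.73 and 36.5 units against the floor, with medians of 0.78 and 0.54 (0.37 at 3 steps and 0 with equal totals). The X-linked testis clusters had a median of 0.36 and 0.01, and for the mean ratios 0.18, the 1.59th percentile of random lists, with -0.13 at 3 steps and 0 with equal totals, and so had the embryonic stem cell clusters, at the 57.3rd percentile. The -0.13 is the ratio of a probe set to 3 grid steps in every pool, since step heights differ, and not lower signal in Tn+ serum. In the X-linked testis clusters miR-547 was higher and miR-465c-5p and miR-743b-3p were lower in both Tn+ pools. None of the Dlk1-Dio3, Sfmbt2 and X-linked testis lists had a member that passed either adjustment in limma (4, 2 and 2 at an unadjusted p under 0.05). Across all 18 lists, 17 had a median above 0 in both Tn+ pools, or 14 with a common floor. The other 3, the nervous system, X-linked testis and embryonic stem cell lists, had a median of 0.01 in Tn+ pool 2 only because its floor is 1.09 against 1.08 units. Of the 18 lists, 2, the lymphocyte and tumour-promoting lists, lay above the central 95% of random lists. The X-linked testis median of 0.18 equalled the lower bound of its random lists, so its 1.59th percentile depends on how ties are counted. By chance 0.9 lists would lie outside. Some lists share members, such as miR-21, so the lists are not separate tests and the count shows no departure from chance. After median-of-ratios, top-100 and equal-total scaling 9, 6 and 4 lists had a median above 0 in both pools.

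**Figure D2:**
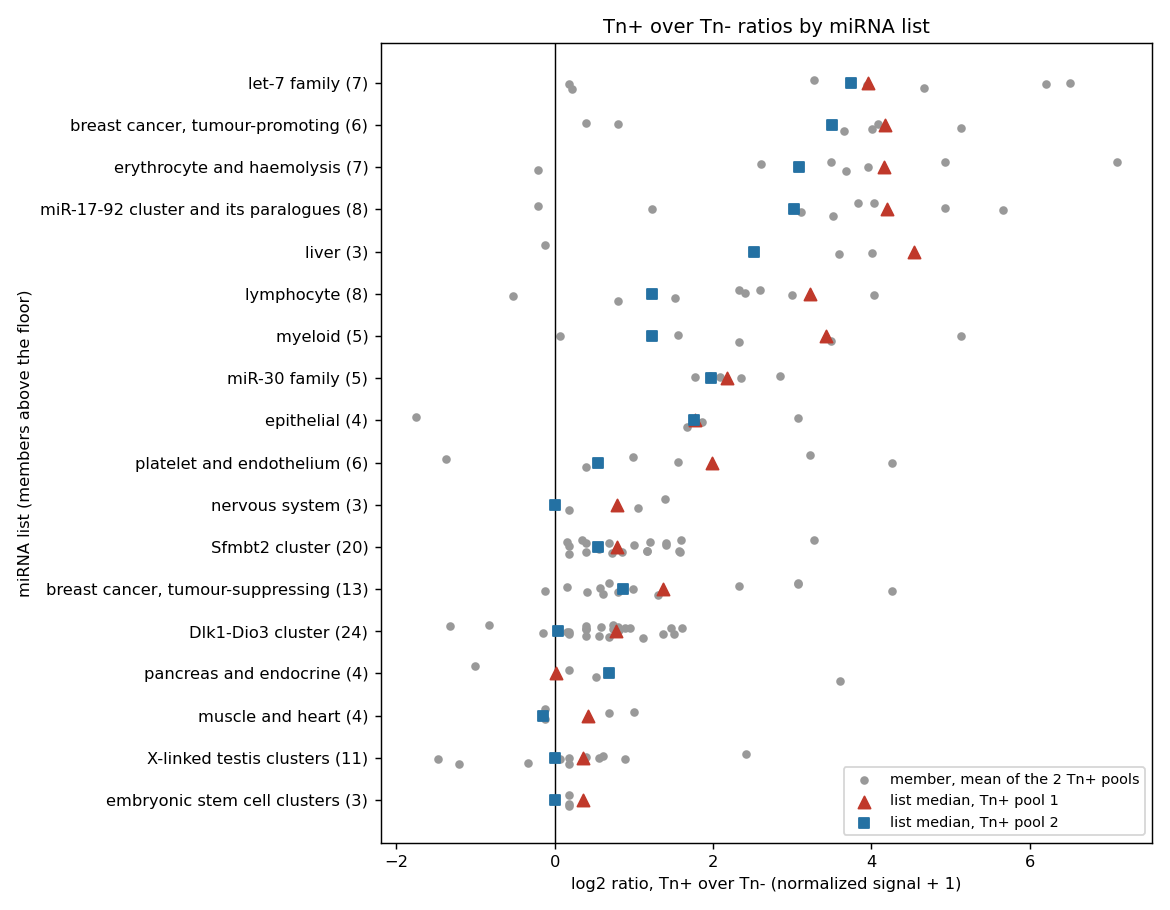
Log2 ratio of Tn+ over Tn- normalized signal (plus 1) for the detected members of 18 miRNA lists, with grey points for members (mean of the Tn+ pools), red triangles for the list median in Tn+ pool 1 and blue squares for Tn+ pool 2; the number of detected members follows each name. Medians in Tn+ pool 1 run from 0.01 in the pancreas and endocrine list to 4.54 in the liver list, and in Tn+ pool 2 from -0.15 in the muscle and heart list to 3.74 in the let-7 family; the muscle and pancreas medians of the mean ratios turn negative after scaling.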

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

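No paired analysis was possible because the groups share only 1 replicate number. The count of miRNAs past an adjusted p of 0.05, 0 over all 566 probes, depended on which probes shared the variance, and the following fits were chosen after seeing the data. It was 29 over the 259 probes above the floor in at least 1 pool and 32 over the 58 probes with a mean of 10 or more, which held all 29. With an intensity trend it was 3 over all probes and 10 over the 259. These calls were all higher in Tn+ serum. In the 58 probes it was 4 with equal totals (2 higher and 2 lower), 0 with top-100 scaling and 0 with median-of-ratios scaling. With a pseudocount of 10 it was 0 over all probes.

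The numbers at least 2-fold higher and lower in both Tn+ pools, 68 and 4, became 10 and 39 with equal totals, 18 and 33 with top-100 scaling, 33 and 21 with the median of ratios, and 35 and 0 with a pseudocount of 10. At 1.5-fold they were 83 and 8, at 3-fold 51 and 1, and among probes with a mean of 10 or more 44 and 0. Leaving out 1 Tn+ pool gave 96 to 120 higher and 7 to 12 lower, with no test possible on 1 pool against 1, since fewer pools had to meet the rule. The share of higher among these calls therefore follows the scaling. Of the 21 lower with the median of ratios, 6 had a mean of 10 or more as deposited. Lists with a median above 0 in both Tn+ pools numbered 17, and 4 with equal totals, 6 with top-100 scaling, 9 with the median of ratios, 14 with a common floor on the deposited scale, chosen after seeing the data, and 17 to 18 with 1 Tn+ pool left out.

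Of 76 named miRNAs, 64 were never reversed under these settings, but 17 of these 64 were at 0 with equal totals. There all pools lay at the common floor, so their difference could not be measured. In equal totals, top-100 and median-of-ratios order, log2 ratios turned to -1.81, -1.04 and -0.11 for miR-223, to -2.03, -1.76 and -1.01 for miR-375, to -0.81, -0.77 and -0.51 for the pancreas and endocrine median, and to -0.24, -0.22 and -0.19 for the muscle and heart median. In equal totals and top-100 order they turned to -0.78 and -0.0027 for miR-1224, -0.40 and -0.18 for miR-129-3p, -1.15 and -0.67 for miR-431, and -1.03 and -0.51 for miR-466j. With equal totals alone, miR-106a with miR-17 turned to -0.22, miR-150 to -0.33 and miR-30e to -0.40. With 1 Tn+ pool left out, ratios ranged from -0.84 to 0.59 for miR-101b, from -0.15 to 0.41 for the muscle and heart median, from -0.34 to 1.37 for miR-375, and from -0.30 to 0.049 for miR-133a and for miR-208a. Signs turned under scaling because each scaling removes a shift in favour of Tn+ serum by construction. The second deposited table changed no value. Positive control scaling, filters and subtraction from negative controls, and count models were not run, since they need counts or control probes. The cause of the other differences was not tested.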

Other observations

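Several miRNAs outside the fixed lists were well measured, and those named here were chosen after their values were seen. miR-22 had 291 and 166 units in the Tn+ pools against 26.4 in the Tn- pool, miR-130a had 129 and 61.6 against 12.4, and miR-378 had 51.8 and 56.1 against 15.6. miR-328 had 33.0 and 42.0 units against 4.81, and miR-1198 had 13.3 and 52.8 against the floor. With equal totals the log2 ratio was -0.31 for miR-22, -0.51 for miR-130a, -1.54 for miR-378, -0.40 for miR-328 and 1.24 for miR-1198. After median-of-ratios scaling these were 1.37, 1.15, 0.12, 1.20 and 2.53. The Tn+ pools also differed from each other. miR-15b was at 226 units in pool 1 and 9.32 in pool 2, and miR-148b at 40.2 units and the floor, while miR-1196 was at 25.9 and 128 units and miR-2137 at 227 and 867.

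The tests below were chosen after the values were seen, except that of neighbouring genes. The first pattern is the higher signal, in both Tn+ pools, of most miRNAs measured in all pools. Red cell miRNA as the whole source was not settled by a count of other markers. The count took all 41 liver, epithelial, myeloid, lymphocyte and platelet markers outside the erythrocyte list, with floors at 3 grid steps. Of these, 10 (miR-122, miR-205 and miR-126-3p among them) were at least 2-fold higher in both Tn+ pools and 0 lower (exact two-sided binomial p = 0.00195 over miRNAs, which are not replicates). A marker near the floor in the Tn- pool could not be counted as lower, nor was miR-200b, with 5.89 units against the floor. The count therefore leaned towards higher and cannot decide, though higher signal was not limited to the erythrocyte list on the deposited scale. This count was run after the medians of 2 subsets had been seen, which depend on how markers are chosen: 3.36 (95% bootstrap interval 2.28 to 4.02) for 12 with a mean of 10 or more, which favours high Tn+ signal, and 0.81 (-0.75 to 3.30) for 10 above the floor in the Tn- pool, which favours high Tn- signal. A difference between pools in RNA amount or recovery, acting as 1 factor on all miRNAs, stays open. Over 58 probes, with floors at 3 grid steps, the Tn+ over Tn- ratios spread 1.22 times as much as the Tn+ pools' own differences would give (0.927 to 1.59). This interval includes 1, but the raised floor gives the lowest Tn- values 1 shared value, which can narrow the spread. The comparison therefore cannot decide. The Tn status of the tumours cannot be told apart from such a factor with 1 Tn- pool.

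The second pattern is that probes whose miRNA has no RefSeq gene had low ratios. With a mean of 10 or more, 6 such probes (miR-1196, miR-1944, miR-2133, miR-2135, miR-2138 and miR-720) had a median log2 ratio of 1.10, against 3.38 for 52 probes with a gene. The difference of -2.28 had a two-sided permutation p of 0.0107 with gene status permuted within 3 classes of level. This test was chosen after the ratios were seen, so its p describes the pattern and gives no separate support for it. A candidate explanation is that these probes report RNA that is not from annotated miRNAs and does not follow the miRNA total. No biological explanation was tested.

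The third pattern concerns miRNA genes within 10 kb of each other, whose products might move together if they share a transcript. Over 16 neighbouring pairs the log2 ratios differed by 1.57 on average, against 2.00 for random pairs (one-sided permutation p = 0.158). Between the Tn+ pools these 16 pairs differed by 1.29 against 1.75 (one-sided permutation p = 0.0964). The prediction had been that a p of 0.05 or more would speak against sharing, but 16 pairs are too few for a missed threshold to exclude it. Within the miR-106b, miR-93 and miR-25 group, miR-106b was higher in Tn+ pool 1 (201 and 53.9 units) and miR-25 higher in Tn+ pool 2 (1868 and 5513).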
